A study of Mus musculus with 20 samples.

How the data were processed

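Poly(A) RNA of whole hippocampus from 20 mice was sequenced as 75-base paired-end reads, per the labels' protocols, with 1 library per mouse and 5 mice in each of 4 groups. The labels call the libraries of a group biological replicates, which is read here as 1 mouse each; if any shared an animal, p-values would measure only the spread between these samples. The deposited values are raw counts of read pairs per gene, 1 file per library, which the authors made with featureCounts 2.0.6, per the file headers. Those headers give read pairs as the unit counted, the GENCODE M34 basic annotation, no strand option and no option to count multi-mapping or multi-overlapping pairs. The submitters' processing notes name STAR 2.5.1, the mm39 genome build, Subread 1.5.1 and DESeq2 1.38.3; the Subread version differs from that in the headers, and the headers are taken here as the record of the counting. Trimming and alignment settings are not given in the sources used here.

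Because the counting ignored strand, a gene and an overlapping antisense gene cannot be told apart, and pairs that map to several near-identical genes were left out. Values of genes with close copies, such as Ifit3, Ifit1, Gbp4, Serpinb1a and Ly6c1, and of the hemoglobin genes, are therefore uncertain. Gene symbols came from a names table made for an older annotation (GRCm38), used for names alone, and all coordinates are those of the files (mm39). Of 57126 gene identifiers 51884 matched a symbol. The 5242 without a match held 0.264% to 0.337% of a library's counts and stayed in the tests under their identifiers.

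Library totals ran from 11493014 to 48267708 read pairs assigned to genes. Counting error is largest for low genes in the shallowest library, and it is part of the spread between mice that the tests measure. Library pairs within a group were compared gene by gene with a chi-square statistic to look for a library deposited in duplicate, and none was found.

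Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 18648. Libraries were scaled by the trimmed mean of M values (TMM), and a quasi-likelihood model with robust settings was fitted to all 20 libraries with 1 term per group. The groups shared 1 estimate of spread because the labels give the same tissue, sex, strain and protocol, which left 16 residual degrees of freedom (median prior degrees of freedom 9.85, biological coefficient of variation 7.08%). The comparisons were dexamethasone against PBS in each genotype, knockin against wild-type under each treatment, and the difference of the dexamethasone responses (interaction). P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at adjusted p below 0.05. Levels are given as TMM-scaled CPM with SD. Sums over liver and neutrophil markers use CPM of the library total without TMM scaling.

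The ratio of responses is the slope, through the origin by total least squares, of knockin on wild-type log2 fold changes. It was taken over genes called for the mean response of both genotypes, so that neither genotype alone chose the genes. This choice favours genes whose responses have the same direction. The error of the slope came from leaving out each library (jackknife). For 30 gene lists with 496 distinct members, 8 of them on 2 lists, camera (limma 3.58.1) was run on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation and with fry. Its p-values were adjusted over the lists of a comparison. The lists cover receptor-induced genes, receptors and stress axis (HPA axis), circadian clock, immediate-early genes, inflammation, interferon response, heat shock, cell death, glutamate, GABA, neurotrophic and monoamine signalling, neurogenesis, cell types of the hippocampus and its surroundings, blood, substrain genes, extracellular matrix and metabolism. Genes within 10 Mb of Nr3c1 were compared with the rest by Fisher's exact test.

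The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names, in each comparison, Nr3c1, the 8 largest rises and 8 largest falls and up to 4 called members per list. The rises and falls were taken among called genes with mean log2 CPM of at least 1, groups that do not overlap and a symbol that is not a gene model name. In the dexamethasone comparisons any member of the receptor-induced list may also be named, and in the genotype comparisons any called gene within 10 Mb of Nr3c1. Srebf1, Ttr, Sele, Alb, Cacng5, Csf3r and the genes of the last part other than Cd74 and H2-Aa were chosen after their values were seen. Values of some single genes are not reported here. The alternatives fixed beforehand were DESeq2 1.42.0 (size factors alone, and its Wald test), limma-voom with sample quality weights, no low-count filter, a filter of 50 counts in 5 libraries, fits to the compared libraries alone, the replicate number as a block, 1 surrogate variable (sva 3.50.0), a threshold of 0.01, other windows around Nr3c1 and each library left out in turn. Chosen after seeing the data were fits without the libraries that carry liver or choroid plexus transcripts, with a choroid plexus covariate, or without the liver-bearing libraries and knockin PBS replicate 4, and list tests with libraries left out.

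The scripts were tested on simulated counts with the real means and library sizes (seed 11) in which 200 genes were changed, or 400 for the slope. For the wild-type response, over 18457 genes, 73% of 100 genes changed 1.5-fold and 89% of 100 changed 2-fold were called. For the PBS genotype comparison the shares were 57% and 85%, over 18457 genes, and for the interaction 64% and 79%, over 18448. Each comparison had 1 run with its own random genes. Counts were drawn independently per gene, so the shares take no account of structure shared by the genes of a library. The adjusted threshold eases as more genes change, so the shares overstate how often a lone changed gene would be called. A simulated slope of 0.8 came out as 0.787. Sequence-level checks of the mutated start codons need reads, which were not analysed here.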

Results

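Hippocampal RNA was sequenced from 20 adrenalectomized male C57BL/6 mice, 5 in each of 4 groups that cross genotype with treatment. Wild-type mice carry the unmodified glucocorticoid receptor gene Nr3c1, whose messenger RNA is translated from several start codons into a full-length protein and N-terminally shorter forms. Homozygous knockin mice carry an Nr3c1 exon 2 in which the start codons of the 7 shorter forms are mutated, so that the full-length form, GRA, is the form left. Removal of the adrenal glands takes away the main source of circulating glucocorticoid. At 2 weeks after surgery the mice received phosphate-buffered saline (PBS) or the synthetic glucocorticoid dexamethasone at 1 mg per kg, and tissue was taken 6 h later. The libraries held from 11493014 (knockin PBS replicate 5) to 48267708 (knockin dexamethasone replicate 1) read pairs assigned to genes, and 18648 genes passed the filter on low counts. Libraries within a group differed by more than sampling noise in all 40 pairs (chi-square per gene 2.58 to 12.9), so none was a duplicate of another. The first principal component, with 26.2% of the variance, placed all 10 dexamethasone libraries on the other side of 0 from all 10 PBS libraries.

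Nr3c1, the targeted gene (ENSMUSG00000024431.16, mm39 chromosome 18, 39543598 to 39623727, minus strand), was transcribed in all 4 groups. Its level was 136 ± 21.8 CPM (read count scaled to library size; SD, n = 5) in wild-type PBS and 98.6 ± 8.27 CPM in wild-type dexamethasone libraries. In knockin libraries it was 163 ± 24.1 CPM under PBS and 111 ± 8.69 CPM under dexamethasone. Dexamethasone lowered it in both genotypes, by a log2 fold change of -0.46 (SE 0.11, edgeR adjusted p = 0.0112) in wild-type and -0.55 (SE 0.11, adjusted p = 0.00227) in knockin mice. The knockin level was 0.26 log2 units above wild-type under PBS (SE 0.11, unadjusted p = 0.026, adjusted p = 1.0), which did not pass the test. Counts summed over the whole gene cannot show the mutated start codons, so this value checks neither the genotype labels nor the protein forms.

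The first comparison asked which hippocampal genes respond to dexamethasone when every receptor form can be made. In wild-type mice the largest rises were in Lao1, an L-amino acid oxidase gene, Plin4, which encodes a lipid droplet coat protein, and Cdkn1a, which encodes the cell cycle inhibitor p21. Plin4 (mm39 chromosome 17, 56407591 to 56416803) went from 1.33 ± 0.366 to 55.4 ± 13.2 CPM (SD, n = 5), a log2 fold change of 5.39 (SE 0.22, edgeR adjusted p = 2.52e-11). Lao1 rose by 6.46 on the log2 scale (SE 0.57), Cdkn1a by 3.71 (SE 0.32) and the secreted phospholipase gene Pla2g3 by 3.34 (SE 0.31). The hypoxia-inducible factor gene Hif3a rose by 3.00 (SE 0.17), Tekt4 by 2.94 (SE 0.23) and the flavin monooxygenase gene Fmo2 by 2.84 (SE 0.33). The largest falls were smaller. The extracellular matrix gene Tnc, tenascin C, fell by 1.81 on the log2 scale (SE 0.27, edgeR adjusted p = 0.000155), from 12.6 ± 3.84 to 3.57 ± 0.659 CPM (SD, n = 5). The amino acid transporter gene Slc38a5 (-1.66, SE 0.19), Insc (-1.46, SE 0.18), the fibroblast growth factor receptor-like gene Fgfrl1 (-1.44, SE 0.08) and Serpinb1a (-1.44, SE 0.15) also fell. So did Mboat1 (-1.44, SE 0.17), Syt15 (-1.35, SE 0.22) and Gbp4 (-1.34, SE 0.24).

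In all, 1717 of 18648 genes changed in wild-type mice at adjusted p below 0.05 by edgeR's quasi-likelihood test, 983 higher and 734 lower. Of these, 161 were at least 2-fold higher and 79 at least 2-fold lower. The values of both groups did not overlap for 1257 of the called genes and for 8.22% of all genes tested, against 0.794% by chance. Lcn2, the lipocalin gene induced in inflammation, was 3.17 log2 units higher (SE 0.90, adjusted p = 0.0353) at 6.66 ± 5.24 CPM (SD, n = 5). That call was lost without any 1 of 7 libraries, which were PBS replicates 2 to 5 and dexamethasone replicates 1, 2 and 5. The lowest value among them was 2.59 (adjusted p = 0.104), without dexamethasone replicate 2. Liver transcripts were high in wild-type PBS replicates 1 and 2, at 287 and 169 CPM summed over 16 marker genes against 4.77 to 59.3 CPM in the other 18 libraries. Without these libraries, a check chosen after seeing the data, 1747 genes were called, 1357 of them among the 1717.

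Genes known to be induced by the glucocorticoid receptor rose as a group in wild-type mice: 25 of the 30 listed members were called higher and none lower (27 higher and none lower when adjusted over the list alone). Their median log2 fold change was 1.05, and camera called the list higher (adjusted p = 2.85e-41). They included the receptor co-chaperone gene Fkbp5 (1.61, SE 0.30), the anti-inflammatory leucine zipper gene Tsc22d3 (1.70, SE 0.13), the kinase gene Sgk1 (1.47, SE 0.12) and the metallothionein gene Mt2 (1.54, SE 0.17). Pdk4 (0.37), Nedd9 (0.31), Dusp1 (0.18), Bcl6 (0.15) and Cebpd (0.50) did not pass. This list's call held with an estimated correlation between genes (adjusted p = 0.0204 with an estimated correlation), the only list in wild-type mice for which it did.

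**Figure D1:**
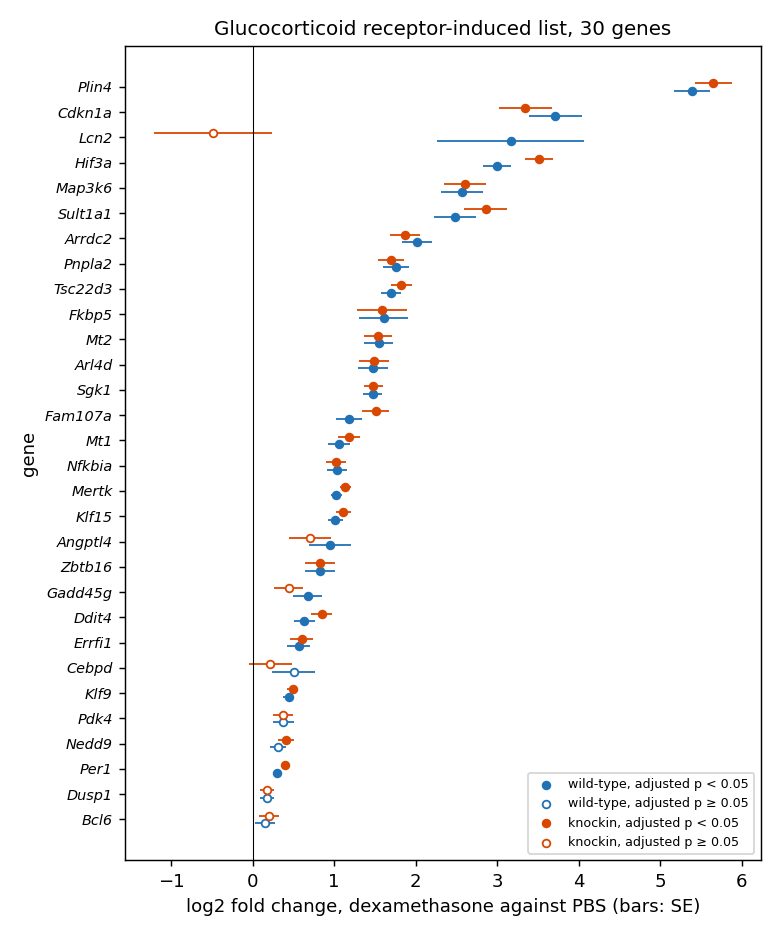
Log2 fold changes of dexamethasone against PBS (x axis) for the 30 genes of the glucocorticoid receptor-induced list (y axis), wild-type in blue and knockin in orange, 5 libraries per group. Points are fitted values, bars are standard errors and filled points passed at adjusted p below 0.05; 25 members were called higher in wild-type and 23 in knockin, and Lcn2 had a value of 3.17 in wild-type and -0.49 in knockin.

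Glial genes moved in both directions in wild-type mice. Of 16 genes of myelin and oligodendrocytes, 8 fell and none rose (10 lower and 1 higher when adjusted over the list alone; camera adjusted p = 5.06e-06, and adjusted p = 0.695 with an estimated correlation). They were led by the oligodendrocyte membrane protein gene Opalin (-1.23, SE 0.11) and included the N-acetylaspartate-cleaving enzyme gene Aspa (-1.04, SE 0.15). Of 10 oligodendrocyte precursor genes, 3 rose, Neu4 (0.51), Vcan (0.41) and Pdgfra (0.19), and none fell (5 higher when adjusted over the list alone). Camera called this list higher (adjusted p = 0.0374, and adjusted p = 0.695 with an estimated correlation), but not without PBS replicate 1 (adjusted p = 0.0713), PBS replicate 2 (0.0586), dexamethasone replicate 1 (0.112) or dexamethasone replicate 5 (0.055). Microglial genes divided: 6 of 15 fell, among them the surface receptor genes Cx3cr1 (-0.62, SE 0.07) and P2ry12 (-0.66, SE 0.09), and 3 rose. The microglial list was not called (camera adjusted p = 0.0727), although it was without PBS replicate 5 (adjusted p = 0.0479), dexamethasone replicate 1 (0.0266) or dexamethasone replicate 2 (0.017). Among 14 astrocyte genes 4 rose, led by the connexin gene Gjb6 (1.32, SE 0.10) and the angiotensinogen gene Agt (0.93, SE 0.12), and 2 fell, among them the water channel gene Aqp4 (-0.40, SE 0.05). Adjusted over the list alone, 4 astrocyte genes were higher and 3 lower. In the endothelial list 3 of 15 rose and 2 fell, with the glucose transporter gene Slc2a1 (1.18, SE 0.15) the largest rise.

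The interferon response list fell in wild-type mice by camera (median log2 fold change -0.22, adjusted p = 0.000145, and adjusted p = 0.496 with an estimated correlation). Of its 15 members 3 were called lower, Ifitm3 (-0.54, SE 0.12), Irf9 (-0.36, SE 0.10) and Ifit3 (-0.75, SE 0.23). The call of Irf9 was lost without wild-type PBS replicate 5 (-0.32, adjusted p = 0.0509). That of Ifit3 was lost without any 1 library but dexamethasone replicate 3, with the highest adjusted p, 0.139, without dexamethasone replicate 1 (-0.65). In the circadian clock list 5 of 17 members rose, among them Per1 (0.30, SE 0.05), and 2 fell, Rorb (-0.89, SE 0.09) and Dbp (-0.62, SE 0.08). Neurotrophic factor and receptor genes rose in 5 of 18 cases, among them Igf1r (0.34) and Fgf2 (0.42), without a call of the list (camera adjusted p = 0.0788). Of 20 GABA system genes 1 rose. Monoamine receptor genes had 2 of 20 higher, and glutamate receptor and postsynaptic genes 3 of 29 higher and 1 lower, Grm3 (-0.38). Extracellular matrix genes went both ways, with 5 of 19 higher, among them the collagen gene Col4a1 (0.55), and 2 lower. So did cell death genes, with 3 of 20 higher, among them Fas (0.89), and 2 lower, among them Bcl2 (-0.50).

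In the other lists few members were called in wild-type mice, where 9.21% of all genes tested were called. Metabolism genes had 4 of 23 higher, immediate-early genes 1 higher and 1 lower of 19, and receptors and stress axis genes 1 higher and 1 lower of 15. Inflammation and NF-kappaB genes had 1 of 15 lower, the NF-kappaB inhibitor gene Tnfaip3 (-0.46). Adult neurogenesis had 1 lower of 15, CA1 1 higher of 9, CA2 and CA3 1 lower of 14, and dentate granule neurons 1 lower of 14. The sole calls of the CA1, the CA2 and CA3 and the dentate lists were each lost without some single library. So was each immediate-early call. Interneuron genes had 2 higher of 13, thalamus and habenula 3 higher of 15, and striatum 1 higher and 1 lower of 12. No member was called among 15 heat shock, 15 mural and meningeal, 14 choroid plexus, 6 red blood cell and 5 substrain genes. Adjusted over the list alone, counts differed for the clock (6 higher and 5 lower), cell death (3 and 3), receptors (3 and 1), CA1 (2 and 0), dentate (1 and 1), extracellular matrix (7 and 2) and metabolism lists (6 and 1). Camera called none of these lists in wild-type mice. Choroid plexus transcripts varied between libraries of 1 group: Ttr was at 1632 CPM in wild-type PBS replicate 4, at 1273 CPM in knockin dexamethasone replicate 2, and at 17.4 to 534 CPM in the other 18. The choroid list's median log2 fold change was -1.20 in wild-type and 0.69 in knockin mice with no member called. In wild-type mice camera gave it an adjusted p of 0.0727, and called it lower without PBS replicate 2 (adjusted p = 0.0105) or 3 (0.0192) or dexamethasone replicate 2 (0.00997). A check chosen after seeing the data left out wild-type PBS replicate 4 and knockin dexamethasone replicate 2. In it 1439 genes were called in wild-type and 1485 in knockin mice.

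**Figure D2:**
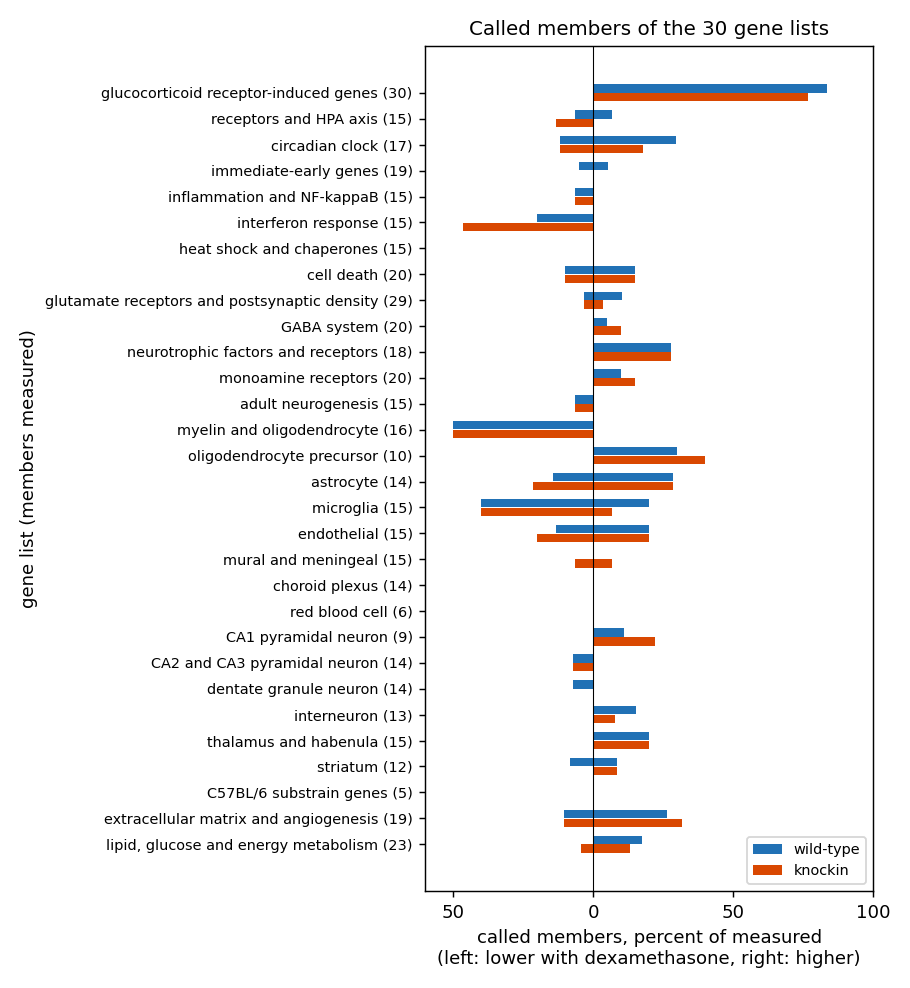
Share of the measured members of each of 30 gene lists (y axis, members measured in brackets) called at adjusted p below 0.05 with dexamethasone (x axis, percent; higher to the right of 0, lower to the left), wild-type in blue and knockin in orange, 5 libraries per group. In both genotypes the receptor-induced list had the most members called higher and no myelin gene was called higher.

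The second comparison asked which genes respond when full-length GRA is the form left. In knockin mice the largest rises were again in Lao1 (log2 fold change 6.92, SE 0.60) and Plin4 (5.65, SE 0.23), which went from 1.21 ± 0.388 to 58.7 ± 6.12 CPM (SD, n = 5). Pla2g3 rose by 3.69 (SE 0.31), Hif3a by 3.51 (SE 0.18), Tekt4 by 3.40 (SE 0.24), Cdkn1a by 3.35 (SE 0.32), Fmo2 by 2.90 (SE 0.34) and the sulfotransferase gene Sult1a1 by 2.86 (SE 0.27). Tnc fell by 1.74 on the log2 scale (SE 0.26, edgeR adjusted p = 0.000162), from 11.8 ± 3.54 to 3.55 ± 1.12 CPM (SD, n = 5). Other large falls were in Serpinb1a (-1.74, SE 0.14), Slc38a5 (-1.64, SE 0.18), the Toll-like receptor homolog gene Cd180 (-1.56, SE 0.19), Gbp4 (-1.46, SE 0.23) and Fgfrl1 (-1.44, SE 0.08). The MHC class II genes H2-Aa (-1.49, SE 0.29) and Cd74 (-1.42, SE 0.28) fell too, and in wild-type mice their values were -0.19 and 0.05, which did not pass. The difference of those responses was -1.30 for H2-Aa and -1.47 for Cd74 (unadjusted p = 0.00403 and 0.00134, adjusted p = 1.0 for both). In all, 1864 genes changed in knockin mice, 985 higher and 879 lower, with 156 at least 2-fold higher and 112 at least 2-fold lower. The values of both groups did not overlap for 1306 of the called genes and for 8.68% of all genes, against 0.794% by chance.

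Of the receptor-induced list, 23 of 30 members rose in knockin mice and none fell (26 higher when adjusted over the list alone; median log2 fold change 1.12). Camera called the list higher (adjusted p = 8.28e-39, and adjusted p = 0.0267 with an estimated correlation). Fkbp5 rose by 1.58 (SE 0.30), Tsc22d3 by 1.82 (SE 0.13), Sgk1 by 1.48 (SE 0.12) and Mt2 by 1.54 (SE 0.17). Lcn2 did not pass in knockin mice (-0.49, SE 0.72, adjusted p = 0.784), and the difference from the wild-type response, -3.65, did not pass after adjustment (unadjusted p = 0.00643, adjusted p = 1.0). The highest PBS value of Lcn2, 15.1 CPM, was in knockin PBS replicate 4, and without that library its fold change was 0.81 (adjusted p = 0.55). Myelin genes again fell, 8 of 16 with none higher (9 lower and 1 higher when adjusted over the list alone), with Opalin at -1.18 (SE 0.10). Camera called the myelin list lower (adjusted p = 2.95e-06, and adjusted p = 0.451 with an estimated correlation). Microglial genes had 6 of 15 lower and 1 higher (8 and 3 when adjusted over the list alone), with Cx3cr1 at -0.73 (SE 0.07) and P2ry12 at -0.62 (SE 0.09). Camera called the microglial list lower (adjusted p = 0.00121, and adjusted p = 0.451 with an estimated correlation).

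Interferon response genes fell in 7 of 15 cases in knockin mice (10 lower when adjusted over the list alone), among them Ifit3 (-1.34, SE 0.23), Ifit1 (-1.29, SE 0.23) and Ifitm3 (-1.02, SE 0.12). Camera called the list lower (median log2 fold change -0.59, adjusted p = 3.75e-07, and adjusted p = 0.148 with an estimated correlation). In mean log2 CPM centred over the libraries, knockin PBS replicates 5 and 4 scored highest of the PBS libraries on this list. Their scores were 0.696 and 0.368, against at most 0.249 in wild-type PBS. Without knockin PBS replicate 5 camera still called the list lower (adjusted p = 9.6e-06). Ifit1 was at -0.57 in wild-type mice (adjusted p = 0.126), and the difference of responses was -0.73 (unadjusted p = 0.0316, adjusted p = 1.0). The inflammation and NF-kappaB list was called lower (camera adjusted p = 0.0199, and adjusted p = 0.451 with an estimated correlation), with 1 of 15 members called and 6 lower when adjusted over the list alone. That call was lost without knockin PBS replicate 4 (adjusted p = 0.132), the library with the highest Lcn2 under PBS. The called member was the receptor gene Tlr2 (-1.24, SE 0.22), at -0.52 in wild-type mice (difference -0.72, unadjusted p = 0.0324, adjusted p = 1.0). Neurotrophic factor and receptor genes were called higher as a list (5 of 18, and 7 when adjusted over the list alone; camera adjusted p = 0.0036, and adjusted p = 0.0632 with an estimated correlation), with Fgfr1 at 0.66 (SE 0.10) and Igf1r at 0.39 (SE 0.05).

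Called members in the other lists in knockin mice were astrocyte 4 higher, with Gjb6 at 1.48 (SE 0.10), and 3 lower of 14, oligodendrocyte precursor 4 higher of 10, and endothelial 3 higher and 3 lower of 15. The circadian clock list had 3 higher and 2 lower of 17, extracellular matrix 6 and 2 of 19, cell death 3 and 2 of 20, and metabolism 3 and 1 of 23. Monoamine receptors had 3 higher of 20, the GABA system 2 higher of 20, glutamate receptors 1 higher and 1 lower of 29, and receptors and stress axis genes 2 lower of 15. Adult neurogenesis had 1 lower of 15, CA1 2 higher of 9, CA2 and CA3 1 lower of 14, and interneurons 1 higher of 13. Thalamus and habenula had 3 higher of 15, striatum 1 higher of 12, and mural and meningeal genes 1 higher and 1 lower of 15. No member was called among the immediate-early, heat shock, dentate granule, choroid plexus, red blood cell and substrain genes. Over all genes tested, 10.0% were called in knockin mice. Adjusted over the list alone, counts differed for the precursor (5 higher), clock (4 higher and 2 lower), GABA (3 higher), monoamine (4 higher), neurogenesis (2 lower), endothelial (3 higher and 6 lower), mural (1 and 5), dentate (3 and 2) and metabolism lists (6 and 1). Camera called none of these other lists in knockin mice. Median, mean and camera direction differed in sign for 4 lists in wild-type mice (receptors, clock, cell death and endothelial) and for 2 in knockin mice (cell death, and CA2 and CA3), none of them called.

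**Figure D3:**
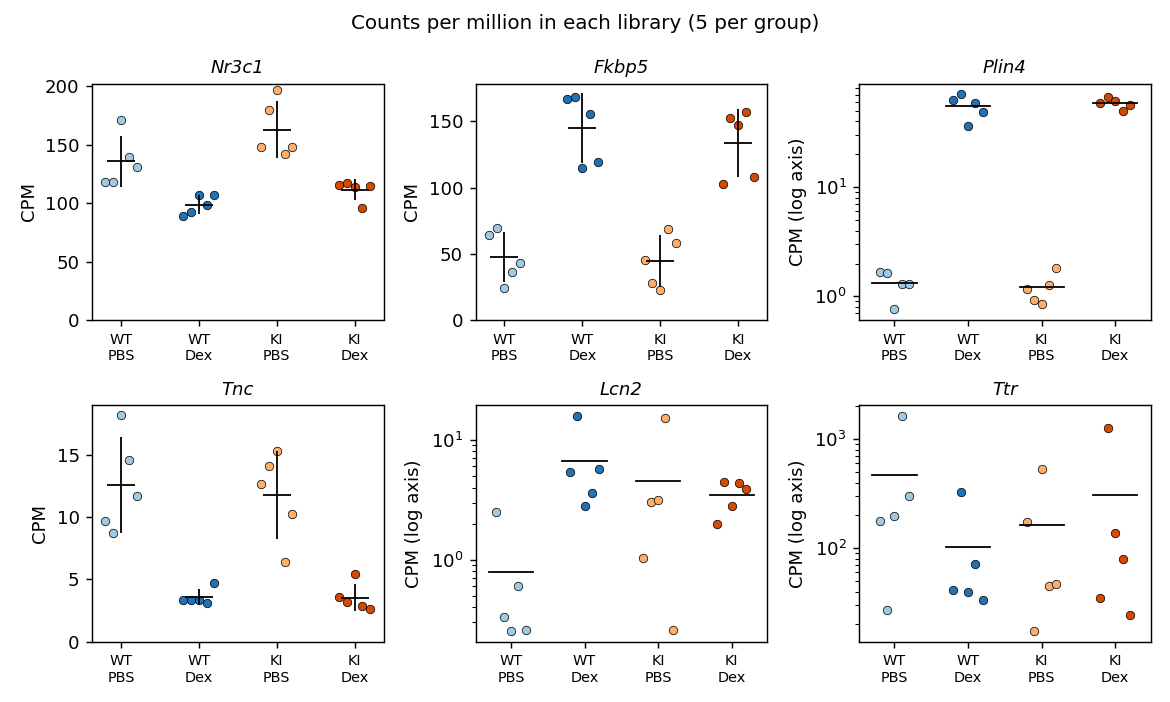
Scaled read counts (CPM, y axis, log axes for Plin4, Lcn2 and Ttr) of 6 genes in each of the 20 libraries, by group (x axis; WT wild-type, KI knockin, Dex dexamethasone). Points are libraries, horizontal lines are group means and vertical bars, drawn only on the linear axes of Nr3c1, Fkbp5 and Tnc, are SD; Nr3c1 had a mean of 136 CPM in wild-type PBS and 98.6 CPM in wild-type dexamethasone libraries.

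The genotype comparison under PBS asked whether the knockin changes the hippocampus without added glucocorticoid. Fkbp5 was at 47.5 ± 19.0 CPM in wild-type and 44.6 ± 19.6 CPM in knockin PBS libraries (SD, n = 5), and Plin4 at 1.33 ± 0.366 and 1.21 ± 0.388 CPM. Lcn2 was at 0.794 ± 0.973 and 4.52 ± 6.06 CPM (log2 difference 2.73, SE 0.92, unadjusted p = 0.00871, adjusted p = 1.0). Camera did not call the receptor-induced list (adjusted p = 0.858), but called it higher in knockin mice without the liver-bearing wild-type PBS replicates 1 and 2 (adjusted p = 0.0479), a check chosen after seeing the data. In mean log2 CPM centred over the libraries, replicates 1 and 2 scored highest of wild-type PBS on this list. Their scores were -0.538 and -0.537, against -0.999 to -0.767 in the others, so leaving them out lowers the wild-type side. On the knockin side, PBS replicate 4 scored highest (-0.340), against -0.867 to -0.648 in the other knockin PBS libraries. Whether the list would be called without that library too was not tested. No gene differed by edgeR's quasi-likelihood test, with 673 genes at an unadjusted p below 0.05, where 932 would be met by chance, and a smallest adjusted p of 0.833. DESeq2 and limma-voom also called 0 genes (787 and 610 at an unadjusted p below 0.05). No member of any of the 30 lists was called, over all genes or when adjusted over the list alone. Of the 9 substrain genes 5 were measured, too few to show whether both genotypes share a C57BL/6 substrain. Camera called the choroid plexus list lower in knockin PBS libraries (median log2 difference -0.98, adjusted p = 0.000267, and adjusted p = 0.765 with an estimated correlation), but not without wild-type PBS replicate 4 (-0.29, adjusted p = 0.272). It also called the mural and meningeal list lower (-0.11, adjusted p = 0.0269, and adjusted p = 0.765 with an estimated correlation). That call was lost without wild-type PBS replicate 4 (adjusted p = 0.318), knockin PBS replicate 2 (0.264) or knockin PBS replicate 4 (0.251). The interferon list was not called (median 0.14, camera adjusted p = 0.0526), but it was called higher without wild-type PBS replicate 1 (adjusted p = 0.012), knockin PBS replicate 1 (0.0481), 2 (0.00015) or 3 (0.0354). Knockin PBS replicates 5 and 4 had the highest scores on the interferon list (0.696 and 0.368), against -0.0289 to 0.217 in the other knockin PBS libraries. Fitted differences of 80.9% of genes had 95% intervals inside 1.5-fold. In simulated data of this comparison the test found 57% of 100 genes changed 1.5-fold and 85% of 100 changed 2-fold, so differences of these sizes in single genes could have been missed.

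Under dexamethasone Plin4 reached 55.4 ± 13.2 CPM in wild-type and 58.7 ± 6.12 CPM in knockin libraries, and Fkbp5 145 ± 26.1 and 134 ± 25.8 CPM (SD, n = 5). No gene differed between the genotypes by edgeR (828 at an unadjusted p below 0.05, smallest adjusted p 0.979), DESeq2 (800 at an unadjusted p below 0.05) or limma-voom (1072). When adjusted over the list alone, 2 metabolism genes were lower in knockin mice, among them the lipogenic transcription factor gene Srebf1 (log2 difference -0.22, adjusted p = 0.0142 over the list), and no member of the other lists was. The mural and meningeal list was called lower in knockin mice by camera (median log2 difference -0.34, adjusted p = 0.000193, and adjusted p = 0.912 with an estimated correlation), but not without wild-type dexamethasone replicate 3 (adjusted p = 0.0735). A fit to the 10 dexamethasone libraries alone called 1 gene, Cd74, which encodes the MHC class II invariant chain, lower in knockin mice (log2 difference -1.05, adjusted p = 0.0211). The fit to all libraries did not call it (-1.05, SE 0.29, adjusted p = 1.0). Near Nr3c1, where sequence carried along with the targeted allele would lie, 0 of 207 tested genes within 10 Mb were called in either treatment. At an unadjusted p below 0.05 there were 16 such genes, 7.73% against 7.81% elsewhere (Fisher's exact test, two-sided, p = 1.0).

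The last comparison asked whether the size of the dexamethasone response depends on the shorter receptor forms. The largest responses were shared: Lao1, Plin4, Pla2g3, Hif3a, Tekt4, Cdkn1a and Fmo2 were among the 8 largest rises in both genotypes, and Tnc, Slc38a5, Serpinb1a, Fgfrl1 and Gbp4 among the 8 largest falls. In all, 712 genes rose and 550 fell in both genotypes, where 51.9 and 34.6 would be met in independent lists, and none was called in opposite directions. Of the 1057 genes called in a single genotype, 95.6% had the same sign in the other, and 51.8% had an unadjusted p below 0.05 there. Over the 3393 genes called for the mean response of both genotypes, the slope of knockin on wild-type log2 fold changes was 1.07 (SE 0.10, 95% interval 0.872 to 1.27). The correlation was r = 0.949 across genes, which are not independent replicates. Choosing genes by the mean of both responses also favours like responses, and so raises this value. Among the 1825 genes that rose the slope was 1.04 (SE 0.10), and among the 1568 that fell 1.14 (SE 0.14). Without the wild-type PBS replicates 1 and 2 that carried liver transcripts, a check chosen after seeing the data, the slope was 0.949. The responses share no libraries.

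No gene's response differed between genotypes by edgeR's test of the interaction (0 of 18648, 527 at an unadjusted p below 0.05, where 932 would be met by chance). DESeq2 and limma-voom called 0 as well, with 575 and 609 at an unadjusted p below 0.05. For Tsc22d3 the difference of responses, knockin minus wild-type, was 0.13 (95% interval -0.25 to 0.50), for Sgk1 0.01 (-0.34 to 0.35) and for Fkbp5 -0.02 (-0.92 to 0.88). For Plin4 it was 0.26 (-0.62 to 1.13) and for Fgfrl1 0.01 (-0.23 to 0.24). For Ifitm3, which fell in both genotypes, it was -0.49 (-0.85 to -0.13, unadjusted p = 0.00967, adjusted p = 1.0). Of the 3393 responding genes, 79.3% had an interval of the difference inside 1.5-fold and 92.5% inside 2-fold. The simulated data, drawn without structure shared between genes, gave a recovery of 64% of 100 differences of response of 1.5-fold and 79% of 100 of 2-fold.

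No list member's response differed between genotypes, over all genes or when adjusted over the list alone. Camera called the choroid plexus list for a difference of responses (median 1.81, adjusted p = 0.000196, and adjusted p = 0.917 with an estimated correlation), but not without wild-type PBS replicate 4 (0.53, adjusted p = 0.0826) or knockin dexamethasone replicate 2 (0.50, adjusted p = 0.112). Lists called in a single genotype did not pass for the difference: inflammation and NF-kappaB at camera adjusted p = 0.115, neurotrophic factors 0.308, microglia 0.169 and oligodendrocyte precursors 0.681. The interferon list, called lower in both, had a median difference of -0.13 (camera adjusted p = 0.115, and adjusted p = 0.917 with an estimated correlation). It was called without wild-type PBS replicate 1 (adjusted p = 0.024) or knockin PBS replicate 2 (0.00179), the inflammation list without wild-type PBS replicate 1 (0.0231) or knockin PBS replicates 1 (0.0211) or 5 (0.0427), and the microglial list without wild-type PBS replicate 3 (0.0268). On the interferon list knockin PBS replicate 5 scored highest of the PBS libraries (0.696). Median, mean and camera direction differed in sign for 7 lists under PBS, 7 under dexamethasone and 5 for the difference of responses, none of them called.

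**Figure D4:**
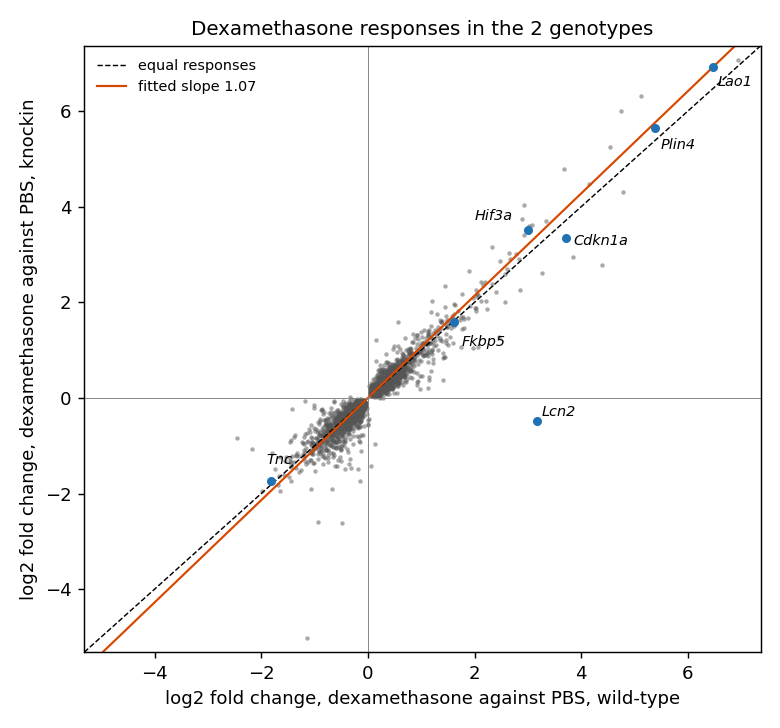
Log2 fold changes of dexamethasone against PBS in knockin (y axis) and wild-type (x axis) mice for the 3393 genes called for the mean response of both genotypes, 1 point per gene. The dashed line marks equal responses and the orange line the fitted slope of 1.07; named genes are in blue, with Lcn2, which was not called for the mean response (adjusted p = 0.139), added at 3.17 in wild-type and -0.49 in knockin.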

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

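The tests of inflammation, liver transcripts and Fkbp5, and the list test with libraries left out, were chosen only after the result was seen. The comparison with other splits of the libraries, the search for single libraries that stand apart and camera's test of the lists were planned.

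The dexamethasone responses were set against 100 splits of the same libraries, the real one included. In wild-type mice the real split called 1717 genes and the highest of the others 120, and in knockin mice 1864 and 118, so that 1 of 100 splits, the real one, gave as many in each and chance is excluded. Under PBS the real genotype split called 0 genes and the highest other split 605, under dexamethasone 0 and 71, and for the interaction 0 and 1. With 0 genes called, all 100 splits give at least as many by construction, and chance is not excluded. The split with 605 genes set wild-type PBS replicates 1 and 2 and knockin PBS replicates 1, 4 and 5 against the other PBS libraries, which points to a structure among the PBS libraries other than genotype. Those replicates were also the PBS libraries with the highest Fkbp5, at log2 CPM 5.50 to 6.11 against 4.51 to 5.44 in the rest. Whether that split and the spread of Fkbp5 share a source was not tested.

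Lcn2, a gene induced by inflammatory cytokines, reached 15.1 CPM and the endothelial adhesion gene Sele 5.45 CPM in knockin PBS replicate 4, the highest of the 10 PBS libraries for both. Whole blood carried in the tissue would raise red cell genes too. The red cell list score of that library was 0.130 (rank 4 of 10), against 0.600 in the highest other PBS library. This score does not decide the question, because it became the deciding value after the neutrophil sum was seen and hemoglobin values are uncertain. Neutrophils without red cells stay open too: neutrophil transcripts summed to 15.2 CPM against at most 10.5 CPM elsewhere under PBS, and without Csf3r, which microglia also express, to 7.26 against 2.38 CPM. An inflammatory reaction in that mouse is a candidate explanation, as 11 of 14 other cytokine-induced genes measured were highest there, where 1.4 would be met by chance (binomial p = 2.73e-09, genes not independent). The design names no such group, and what set off a reaction in 1 mouse cannot be read from the counts. Knockin PBS replicate 4 also scored highest of the 10 PBS libraries on the receptor-induced list, which holds Lcn2. Its score was -0.340, against -0.999 to -0.537 in the others. Whether that score and the cytokine-induced genes share a source was not tested.

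Liver transcripts stood out in wild-type PBS replicates 1 and 2, at 287 and 169 CPM summed over 16 markers (Alb at 124 and 72.5 CPM), against 5.29 to 9.53 CPM in the other wild-type PBS libraries. The remaining 15 libraries ran from 4.77 to 59.3 CPM. Among them were wild-type dexamethasone replicate 2 at 57.4 CPM and knockin dexamethasone replicates 4 and 2 at 49.2 and 44.3 CPM. Lower amounts of liver transcripts thus remained when wild-type PBS replicates 1 and 2 were left out. An effect of the wild-type genotype without dexamethasone that all mice of the group share is argued against, since 0 of the other 3 libraries of that group lay above the remaining 15; an effect in some of them is not. Liver RNA or reads carried into the libraries may be the source, and would give all markers about 1 ratio between both libraries. The ratio had a median of 1.56 (0.973 to 3.93) and a log2 SD of 0.553, between the bounds of 0.5 and 1 set for that test, so that carry-over and a change in the animals cannot be told apart. None of the 15 markers tested was called in the wild-type response.

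Fkbp5 varied under PBS from a log2 CPM of 4.51 (knockin PBS replicate 3) to 6.11 (wild-type PBS replicate 2), against 6.69 to 7.40 under dexamethasone. Residual glucocorticoid with the gene profile of the dexamethasone response would move other responding genes by the same share of their response, but the slope of that share on the share of Fkbp5 was 0.138 (SE 0.0122) over 251 genes of at least 2-fold response and 0.175 (SE 0.0139) over 3392, which argues against full proportion, while a slope above 0 leaves a low steroid level that moves Fkbp5 most open. A neuron share that moves all other cell types alike would give their genes about the same slope on Fkbp5. Over genes without a dexamethasone response the slope was 0.11 (SE 0.03) for 6 astrocyte and -0.10 (SE 0.06) for 4 oligodendrocyte precursor genes, a difference of 0.22 (SE 0.07). It was -0.08 (SE 0.02) for 3 microglial genes, -0.06 (SE 0.08) for myelin, -0.03 (SE 0.04) for endothelial and 0.10 (SE 0.10) for mural genes. Astrocyte and microglial slopes lay more than 2 SE from 0 on opposite sides. The lists compared were picked after the values were seen, so such a neuron share is not excluded. A varying share of hippocampal neurons along with other changes in the dissection cannot be told apart from a low steroid level, because 1 of 37 dentate and CA markers (Cacng5, SD 0.659) varied as much as Fkbp5 (SD 0.616). Centred within genotype, over the 10 PBS libraries Fkbp5 went with the dentate granule list (r = 0.900, permutation p = 0.00047, adjusted 0.00735; rho = 0.891, permutation p = 0.00114, adjusted 0.0118; r = 0.916 without the 2 extreme libraries) and the receptor-induced list without Fkbp5 (r = 0.898, permutation p = 0.00049, adjusted 0.00735; rho = 0.939, permutation p = 0.00026, adjusted 0.0078; r = 0.884), 2 of 11 lists, of 30 tested, with an adjusted p below 0.05 for r; the others of the 7 that passed for rho too were oligodendrocyte precursor (r = -0.851), heat shock (0.829), CA1 (0.850), neurogenesis (-0.800) and astrocyte (0.748).

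Single libraries stood far from the 4 others of their group in 31 of 632 groups of values, where 31.6 would be met by chance, which marks about 1 in 20 groups. These values are log2 CPM. Low or high values in wild-type PBS libraries were Cry1 3.43 and Irf7 1.41 in replicate 1, Opalin 4.53 and Tlr2 -0.11 in replicate 2, Fgfr1 7.01 and P2ry12 5.92 in replicate 3 and Reln 6.15 in replicate 4. In wild-type dexamethasone libraries they were Grm3 5.57 and Rora 5.82 in replicate 1, Ifit1 1.12 in replicate 3, and Tnc 2.27 and Bcl6 5.57 in replicate 5. In knockin PBS libraries they were Plekhg1 5.50 in replicate 3, Ifitm3 3.67 and Mt2 4.97 in replicate 4, and Ncoa1 7.74 and Abcb1a 5.33 in replicate 5. In knockin dexamethasone libraries they were Neu4 3.97 in replicate 3, Nr3c1 6.59, Pmaip1 2.08 and Fam107a 10.03 in replicate 4, and Ifitm3 2.71 in replicate 5. Scores of lists, as mean log2 CPM centred over the libraries, stood apart for thalamus and habenula 0.209 in wild-type PBS replicate 2, microglia 0.212 in replicate 3 and cell death -0.113 in replicate 4. In wild-type dexamethasone libraries they did for cell death 0.0505 in replicate 1 and myelin -0.518 in replicate 3. In knockin dexamethasone libraries they did for choroid plexus 2.18 and interneurons -0.0855 in replicate 2, and interferon response -0.141 and endothelial 0.0679 in replicate 5. The choroid plexus list also differed in its response between genotypes, by a median of 1.81 log2 units in camera's test of the difference. That call was lost with an estimated correlation (adjusted p = 0.917), without wild-type PBS replicate 4 (adjusted p = 0.0826) and without knockin dexamethasone replicate 2 (adjusted p = 0.112), the libraries with the most Ttr.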

How the results depend on the processing

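Fits without liver-bearing or choroid-rich libraries, with a choroid covariate or without knockin PBS replicate 4, and lists with libraries left out, were chosen only after the result was seen; the other settings were planned. Of 197 called results of named genes, 0 changed direction in any setting that measured them. Of those not called, Lcn2 in knockin mice (-0.49) turned to 0.59 by limma-voom, 0.81 without knockin PBS replicate 4 and 0.81 without that and the liver-bearing libraries, and the difference of responses of Nr3c1 (-0.09) to 0.03 without the liver-bearing libraries. At a threshold of 0.01 the counts fell to 1008 (wild-type) and 1175 (knockin). Under dexamethasone, the fit to the compared libraries alone called 1 gene between genotypes (Cd74). Its fold change was the same in both fits (-1.05), so the fits differ in the estimated spread and the adjustment. The SD of Cd74 was 2.78 and 1.97 CPM in wild-type and knockin PBS libraries, against 1.03 and 0.469 CPM under dexamethasone. The slope moved from 1.07 to 0.949 without the liver-bearing libraries; the cause was not tested. In all other settings, apart from single libraries left out, both response counts stayed within 1.5 times. They ran from 1439 to 1997 in wild-type and 1485 to 2017 in knockin mice. In the same settings the 3 comparisons between genotypes stayed at 0, and slopes ran from 0.983 to 1.13. DESeq2's Wald test shared 1667 and 1818 calls with edgeR, and limma-voom 1593 and 1762. Without each library in turn, counts ran from 1288 to 1692 (wild-type) and 1501 to 1955 (knockin), from 0 to 0 for the 3 genotype comparisons, and the slope from 1.01 to 1.12; of 197 called gene results 29 lost their call without some single library. Windows of 5 and 20 Mb around Nr3c1 held 0 called genes. The labels share replicate numbers across groups, but same-numbered libraries did not correlate as a rule (mean correlation 0.018, against -0.0044 for other pairs). The correlation was over 0.1 in 6 of 30 same-number pairs, and 7 of 20 libraries correlate best with their own number. The highest same-number value was 0.371 and the highest other 0.331, so pairing of some libraries is not excluded. With the replicate block the counts were 1643, 1843, 0, 0 and 0 and the slope 1.08; the block added camera calls of the mural list in knockin mice (adjusted p = 0.0423) and the interferon list under PBS (0.0214) and changed no other list call. Fry, which asks whether a list moves without comparing it with other genes, called 7 lists in wild-type and 11 in knockin mice and 0 in the genotype comparisons. Lists not called by camera gained a call without some single library in 3 cases in wild-type and 5 in knockin mice, 5 under PBS, 4 under dexamethasone and 4 for the difference of responses. Without the liver-bearing libraries the precursor list in wild-type mice lost its call (adjusted p = 0.192), and the receptor-induced (0.0479) and interferon (0.0298) lists gained one between genotypes under PBS, as did the inflammation and interferon lists for the difference of responses (0.0466 each) and the microglial (0.039) and choroid (0.00829) lists in wild-type mice. Without the choroid-rich libraries the choroid list lost its calls under PBS (0.192) and for the difference (0.801) and the mural list under PBS (0.318), while the monoamine and mural (0.0447 each) and interneuron (0.0342) lists in knockin mice and the inflammation list for the difference (0.0348) gained one; the cause was not tested. Without a low-count filter, which adds genes to the adjustment, 1522 and 1746 genes were called.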

Other observations

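Except for Cd74 and H2-Aa, which the rule for named genes gave, the genes in this part were chosen only after the result was seen, and no further tests were made of them beyond the fits already described.

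Several genes on none of the lists changed in both genotypes. Mfsd2a, the blood-brain barrier transporter of lysophosphatidylcholine-bound omega-3 fatty acids, went from a mean of 14.2 to 58.4 CPM in wild-type and from 13.0 to 58.4 CPM in knockin mice (log2 fold change 2.05, SE 0.08, edgeR adjusted p = 3.55e-14, and 2.18, SE 0.08, adjusted p = 1.43e-14). The volume-regulated anion channel genes Lrrc8a (0.81 and 0.96 in wild-type and knockin) and Lrrc8c (0.87 and 0.78) rose, as did the iron oxidase gene Heph (1.49 and 1.64), the syndecan gene Sdc4 (1.23 and 1.36) and the secreted protease gene Htra1 (1.15 and 1.33). The Wnt receptor gene Fzd2 rose (1.57 and 1.71) and the hedgehog transcription factor gene Gli3 (-0.80 and -1.25), the neural stem cell nuclear receptor gene Nr2e1 (-0.84 and -0.86) and the RNA gene Sox2ot (-0.96 and -0.99) fell. The urea transporter gene Slc14a1 (-0.97 and -1.03) and the G-protein regulator gene Rgs20 (-1.08 and -1.14) fell too. The adhesion gene Kirrel2 rose by 1.76 and 2.18. No difference of responses passed among these genes by edgeR. The differences of Gli3 (-0.45, unadjusted p = 0.00285, edgeR adjusted p = 1.0) and Kirrel2 (0.42, unadjusted p = 0.00629, edgeR adjusted p = 1.0) had the smallest unadjusted p.

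Of 8 MHC class II and related genes, 5 fell in knockin mice: Cd74 (-1.42), H2-Aa (-1.49), H2-Ab1 (-1.50), H2-Eb1 (-0.80) and H2-Oa (-1.38), with edgeR adjusted p of 0.00185, 0.00107, 0.011, 0.0485 and 0.0244. In wild-type mice their values were 0.05, -0.19, -0.43, 0.13 and 0.89, none of which passed. The differences of responses were -1.47, -1.30, -1.07, -0.92 and -2.26, and none passed after adjustment over all genes (edgeR adjusted p = 1.0 for each). H2-Oa had group means of 0.151 to 0.502 CPM, near the low end of what was tested. Cd74 was at 2.13 to 3.33 CPM in the 5 knockin and 4.15 to 6.52 CPM in the 5 wild-type dexamethasone libraries, and under PBS at 4.20 to 9.41 CPM in knockin and 3.27 to 10.1 CPM in wild-type libraries. Wild-type PBS replicate 4 and knockin PBS replicate 4 were the highest PBS libraries of their groups for Cd74, H2-Aa, H2-Ab1 and H2-Eb1. The genes H2-DMa (-0.11 and -0.21 in wild-type and knockin), H2-DMb1 (0.17 and -0.25) and the transactivator gene Ciita (0.05 and -0.15) did not pass in either genotype.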
